A study of Pimephales promelas with 30 samples.

How the data were processed

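Total RNA from 26 ovaries and 4 samples of ovulated eggs of the fathead minnow was labelled with 1 dye (Cy3) and hybridised, 1 sample per array, to Agilent arrays of 15208 probes of 60 bases. The labels say that eggs were expressed from the fish before the ovaries were taken out, and that ovaries were sorted by histology. The groups were pre-vitellogenic ovary (n = 6), vitellogenic ovary (n = 7), mature ovary (n = 6), ovulated eggs (n = 4) and atretic ovary (n = 7). Nothing in the labels beyond the group and a number says that replicates are separate fish, so the p-values measure the spread between these samples.

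The deposited scanner files hold an intensity per spot, as a raw mean, a local background median and a processed signal, from Agilent Feature Extraction 9.5 (9.5.1.1 in the file headers). Per the file headers, the processed signal was background-subtracted and detrended within each array, with no scaling between arrays. The authors' value table holds the same processed intensity rounded to 3 digits, with a largest relative difference of 0.498% over all arrays. The deposited files also hold other columns of 0 or 1 per spot, which mark spots well above background, saturated spots, and spots that are not uniform or are outliers in their population.

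Values here are log2 of the processed signal minus the 75th percentile of log2 signal over all probes of the same array, so that 0 is the level of a probe at that percentile. The 536 control spots of each array were set aside. Spots marked as not uniform or as population outliers were left out, with a mean of 6.53% ± 2.59 (SD, n = 30) of the spots of an array. Such spots made up 35.5% of the spots in the brightest 10% of probes, so the bright probes rest on fewer arrays. A probe entered the fit when it was well above background on at least 4 of the 30 arrays, which held for 13471 probes, of which 13418 had a value left. No value was left in at least 1 group for 434 probes.

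The groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 30 arrays, no covariate, and moderated two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over the probes tested in a comparison, and the threshold was an adjusted p of 0.05. The 4 main comparisons were vitellogenic minus pre-vitellogenic ovary, mature minus vitellogenic ovary, ovulated eggs minus mature ovary, and atretic ovary minus the mean of the 3 other ovary groups. Atretic ovary was also compared with each of the 3 other ovary groups, and moderated F tests covered the 5 groups and the 4 ovary groups. These comparisons, their threshold and most alternatives were fixed before the data were examined. Differences of 1 value per array were tested with two-sided exact permutation tests. The values were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the R package data.table (version 1.17.8), and the plots were drawn with matplotlib 3.10.9.

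The files give no gene name: the description of all 15208 probes is Unknown, and 0 probe names were found among the 64593 genes of the reference table. The probes stand for 14499 contigs or sequence reads, of which 709 have 2 probes. The lists of genes and of cell type markers fixed beforehand, with camera and fry as their tests, therefore could not be used, and no genome position is given. Probes are named by their identifier. By a rule fixed beforehand, at most 2 probes per direction and main comparison were named, those with the largest change among probes past the threshold, with a log2 change of at least 1 and well above background on at least 50% of the arrays of both groups. Where 5 or fewer probes passed, the others are named too, and the text says that they were chosen after their values were seen.

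The procedure was tested on simulated data with the same number of arrays per group and no batches. In the comparison of vitellogenic with pre-vitellogenic ovary it recovered 25.4% of probes simulated with a log2 change of 1, 83.6% of those with 2 and 90.9% of those with 3. The figures were 16.4%, 71.6% and 93.9% for mature against vitellogenic ovary, 25.4%, 62.7% and 92.4% for eggs against mature ovary, and 41.8%, 85.1% and 90.9% for atretic against the other ovaries. False calls numbered 5 of 138, 1 of 122, 9 of 129 and 8 of 153 calls in these comparisons. The simulated arrays were independent, with 1 SD per probe shared by all groups. In the data the median SD within a group, on scan day 1, was 0.522 in eggs and 0.291 to 0.352 in the ovary groups. These figures therefore describe simpler data than the real arrays, above all for the eggs. For arrays, the number of samples limits the precision.

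The alternatives were quantile normalization, median centring, no scaling, scaling to 5 of the 10 spike-in controls, normexp background correction with an offset of 50, the deposited value table, other filters on dim probes, keeping the outlier spots, an intensity trend with robust moderation, array weights, fitting the arrays of the compared groups alone, slide or scan day as a block, replicate number as a block, stricter thresholds, and leaving out each array in turn. Fits on 1 scan day, on 1 slide, without pre-vitellogenic arrays 2 and 3 or 2 to 4, with 3 pairs of a mature and an egg array as a block (also without egg array 1), and with at least 2 values left in every group were added after the data were seen. The file headers gave 6 slides and 2 scan days. Spots left out averaged 7.52% ± 1.82 (SD, n = 24) on arrays of scan day 1 and 2.57% ± 0.44 (n = 6) on those of scan day 2. In stages with arrays of both days, bright probes can therefore lean toward scan day 2.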

Results

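Transcript levels were measured in ovaries of the fathead minnow, a small freshwater fish used in toxicology, to ask how gross ovarian stage relates to the transcript profile. The stages were pre-vitellogenic ovary (before yolk uptake, n = 6), vitellogenic ovary (during yolk uptake, n = 7), mature ovary (n = 6), ovulated eggs (n = 4) and atretic ovary (with degenerating follicles, n = 7), with 1 array per sample. On average, 80.2% ± 3.4 (SD, n = 30) of the 15208 probes were well above background, with a range of 73.3% to 86.2%. The 75th percentile of the processed signal ranged from 821 on egg array 1 to 3208, and between 15 and 156 probes per array were saturated. No probe carries a gene name in the files, so probes are given by identifier and sequence, with levels in log2 relative to the 75th percentile of the same array.

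Over the 9675 probes well above background on all arrays, stage accounted for a median of 15.8% of a probe's variance, against a median of 13.2% and a highest value of 16.0% in 20 shuffles of the group labels. Slide accounted for 28.2% (highest shuffle 16.8%) and scan day for 9.17% (highest shuffle 4.13%). The first principal component, with 17.8% of the variance, separated the 6 arrays of scan day 2 (scores of 37.1 to 48.6) from the 24 of scan day 1 (-44.2 to 2.65). Scan day 2, which is also slide 6, held 2 pre-vitellogenic, 2 mature and 2 atretic ovaries, and no vitellogenic ovary or eggs. Egg array 1 had a score of 102.8 on the second component, which carried 13.2% of the variance. On the third component, with 9.48% of the variance, pre-vitellogenic arrays 2, 3 and 4 had scores of 49.2, 29.2 and 40.1, and no other array was above 14.1. Within pre-vitellogenic, mature and atretic ovary, 3950 of 13151 probes differed between the scan days (limma, adjusted p under 0.05), 2442 of them higher on day 2.

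**Figure D1:**
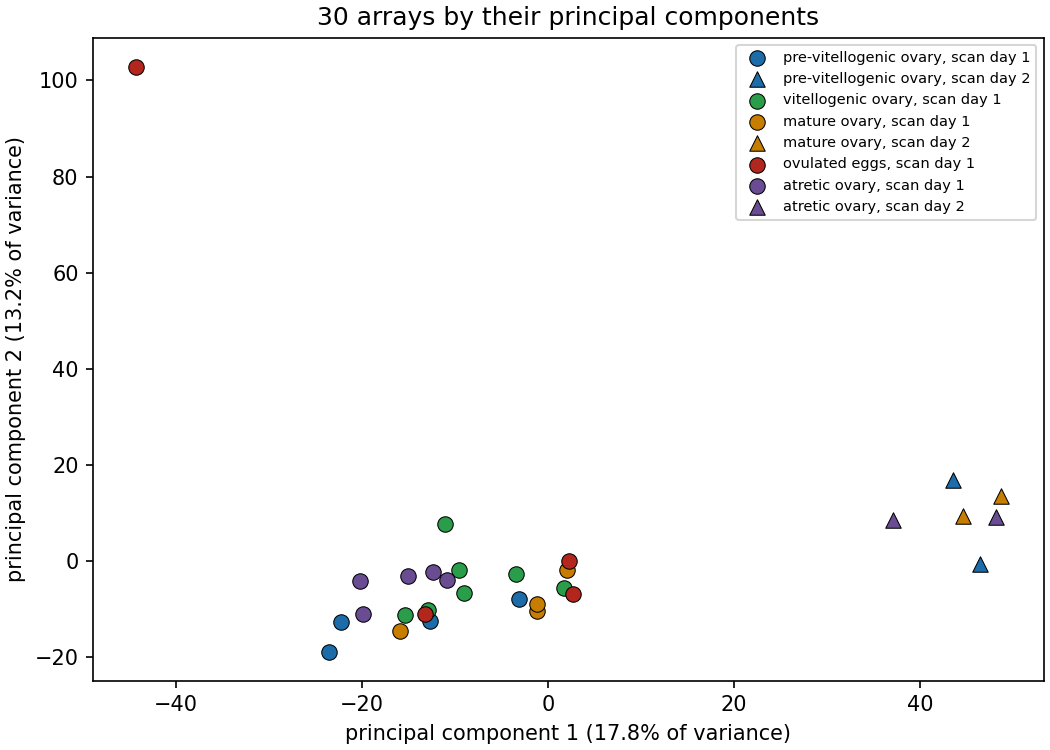
Scores of the 30 arrays on the first and second principal components of log2 levels of 9675 probes, with colour for the stage and symbol for the scan day. The 6 arrays of scan day 2 lie at 37.1 to 48.6 on the first component, and egg array 1 lies at 102.8 on the second.

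Vitellogenic ovary was compared with pre-vitellogenic ovary to ask which transcripts differ between ovaries before and during yolk uptake. Of 13136 probes tested, 38 passed the threshold, 29 of them higher and 9 lower in vitellogenic ovary. The measured rises had a median of 5.95-fold (range 1.62 to 16.6) and the 9 falls a median of 2.35-fold (1.48 to 3.76). Of the 29 rising probes, 17 were well above background on all 6 pre-vitellogenic arrays, with a median rise of 2.94-fold. The other rises include pre-vitellogenic values not well above background. The folds depend on how background is handled. With normexp and the 75th percentile the median over all 29 was 2.04-fold, and it was not taken for the 17 alone. Relative to the mean of the group means, the 29 rising probes averaged -1.25 ± 0.54 (SD, n = 6) in pre-vitellogenic, 1.01 ± 0.41 (n = 7) in vitellogenic, 0.32 ± 0.22 (n = 6) in mature and 0.18 ± 0.68 (n = 7) in atretic ovary, and -0.31 ± 1.08 (n = 4) in eggs. Without egg array 1 (-1.89) the egg mean was 0.21 ± 0.30 (SD, n = 3). The 9 falling probes averaged 0.75 ± 0.25 in pre-vitellogenic, -0.42 ± 0.34 in vitellogenic, 0.05 ± 0.06 in mature and -0.20 ± 0.18 in atretic ovary, and -0.23 ± 0.09 in eggs. Both sets were chosen for the difference between the first 2 of these groups.

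The largest rise was that of UF_Ppr_AF_105925 (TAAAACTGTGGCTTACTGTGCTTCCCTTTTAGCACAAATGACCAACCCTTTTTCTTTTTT), from -7.47 ± 1.04 (SD, n = 6) to -3.42 ± 1.00 (n = 7), a log2 change of 4.05 ± 0.69 (SE) with an adjusted p of 0.0127. It was well above background on 3 of 6 pre-vitellogenic and 7 of 7 vitellogenic arrays, so the size and rank of this rise depend on how background is handled. With normexp it was 1.68 (adjusted p = 0.108) with the 75th percentile and 1.75 (adjusted p = 0.0159) with quantile normalization, and over 49 other fits the adjusted p ranged from 0.00114 to 0.667. UF_Ppr_AF_115695 (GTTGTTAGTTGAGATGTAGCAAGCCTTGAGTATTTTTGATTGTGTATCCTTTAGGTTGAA) rose from -6.27 ± 2.07 to -2.39 ± 0.90, by 3.88 ± 0.82 (SE, adjusted p = 0.0367). Pre-vitellogenic array 3 was at -2.87, within the vitellogenic range (-3.49 to -1.60), and array 2, at -9.10, was not well above background. UF_Ppr_AF_115695 did not pass with scan day as a block (3.52, adjusted p = 0.0608), with slide as a fixed block (3.43, adjusted p = 0.0751) or with normexp and the 75th percentile (1.95, adjusted p = 0.105), and over 49 other fits its adjusted p ranged from 0.0102 to 0.886. UF_Ppr_AF_111654 (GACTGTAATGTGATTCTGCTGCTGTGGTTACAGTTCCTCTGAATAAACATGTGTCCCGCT) went from -2.13 ± 0.62 to -4.04 ± 1.12, a change of -1.91 ± 0.39 (SE, adjusted p = 0.0367). It did not pass with scan day as a block (-1.80, adjusted p = 0.0551) or on the compared arrays alone (adjusted p = 0.0902), within a range of 0.011 to 0.729 over 49 other fits. UF_Ppr_AF_109599 (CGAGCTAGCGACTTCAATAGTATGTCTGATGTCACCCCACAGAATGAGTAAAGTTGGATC) went from -3.28 ± 0.31 to -4.88 ± 0.48, a change of -1.60 ± 0.34 (SE, adjusted p = 0.0382). It passed with scan day as a block (adjusted p = 0.0115) and with slide as a fixed block (0.00667), and not with normexp and the 75th percentile (-1.05, adjusted p = 0.102), within a range of 0.00667 to 0.992.

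The number of probes called between these 2 stages moved with the fit: 22 (16 higher, 12 shared with the 38) with scan day as a block, 24 (17 higher, 7 shared) with slide as a fixed block, 145 (123 higher, 26 shared) on scan day 1 alone, 1 without pre-vitellogenic arrays 2 and 3, 0 without pre-vitellogenic arrays 2, 3 and 4, and 0 with scaling to the spike-ins. Without arrays 2, 3 and 4 the changes of the named probes were 3.30 (UF_Ppr_AF_105925), 3.80 (UF_Ppr_AF_115695), -2.29 (UF_Ppr_AF_111654) and -1.48 (UF_Ppr_AF_109599), in a group of 3 arrays. Scan day 2 held no vitellogenic ovary, so the difference has no value there. The share that rose, 76.3% of the 38, also moved with the scaling: 34 higher and 21 lower with quantile normalization, 32 and 38 with median centring, 14 and 0 without scaling. Single arrays moved the count as well. It was 89, 5, 3 and 24 without pre-vitellogenic arrays 1, 2, 4 and 5, and 113, 9, 15, 10, 10 and 6 without vitellogenic arrays 1, 2, 3, 4, 5 and 7. It was 191 without egg array 1, and 65 and 75 without atretic arrays 2 and 7. These arrays are in neither group and enter the comparison only through the shared estimate of spread.

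**Figure D2:**
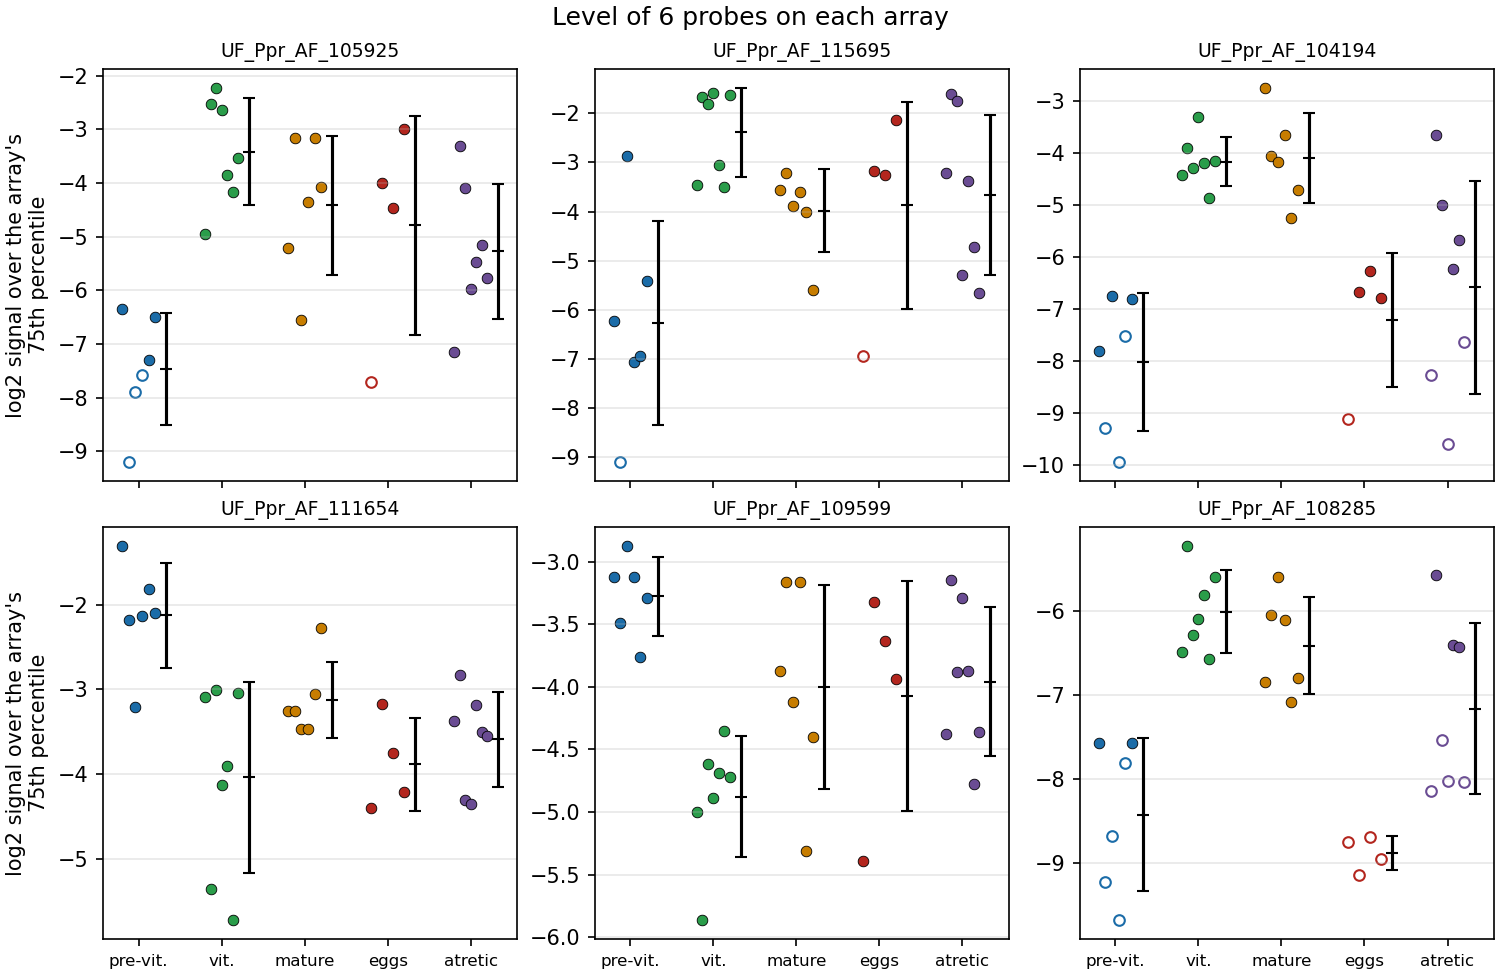
Log2 level of 6 named probes relative to the 75th percentile of the same array, by stage, with 1 point per array and a bar for the mean with its SD; open symbols are values not well above background. UF_Ppr_AF_105925 averaged -7.47 in pre-vitellogenic and -3.42 in vitellogenic ovary.

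Mature ovary was compared with vitellogenic ovary to ask what changes from yolk uptake to maturity. With limma, 0 of 13121 probes passed the threshold, and the smallest adjusted p was 0.931. At an unadjusted p under 0.05 there were 573 probes, 4.37% of those tested. Without mature array 6, 1 probe passed, and the count was 0 in every other fit. UF_Ppr_AF_105925 averaged -4.42 ± 1.30 (SD, n = 6) in mature ovary and UF_Ppr_AF_115695 -3.98 ± 0.84, between their pre-vitellogenic and vitellogenic means.

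Ovulated eggs were compared with mature ovary, which holds follicle and other tissue besides the oocytes. Of 13095 probes tested, 4 passed, all with a lower egg value, and 905 (6.91%) had an unadjusted p under 0.05, of which 302 were higher and 603 lower. The median change of all probes was -0.10. It was -0.64 with spike-in scaling and 0.13 with normexp and the 75th percentile, so the split of the 905 by direction is not read as a result. For 3 of the 4 probes the egg value came from egg array 1 alone, since the spots of the other 3 egg arrays had been left out as outliers. Their tests assume that this lone array varies like the arrays of the other groups, so they do not compare eggs in general with mature ovary. These were UF_Ppr_AF_105883 (log2 change -3.44, adjusted p = 0.00414), UF_Ppr_AF_117454 (-3.37, adjusted p = 0.00185) and UF_Ppr_AF_108220 (-2.62, adjusted p = 0.00414). A second probe of the contig of UF_Ppr_AF_105883 differed by -0.11 (adjusted p = 0.903). With the outlier spots kept, the changes of the 3 probes were -0.89, -0.81 and -0.58 (adjusted p = 0.672 each), and UF_Ppr_AF_105883 was at 3.18, 3.08 and 3.17 on egg arrays 2 to 4, against a mature mean of 3.21. UF_Ppr_AF_108285 (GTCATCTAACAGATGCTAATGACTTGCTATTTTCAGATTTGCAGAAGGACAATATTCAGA) was well above background on 6 of 6 mature ovaries and on 0 of 4 egg arrays. On the processed signal it was at least 1.7-fold lower in eggs, a bound that was not tested. The measured log2 change of this probe was -2.47 (limma, adjusted p = 0.0398). It passed in 22 of 49 other fits, and not with quantile normalization (adjusted p = 0.069), slide as a fixed block (0.0724), scan day as a block (0.0797) or normexp and the 75th percentile (log2 change -0.12, adjusted p = 0.967), within a range of 0.0104 to 0.967. UF_Ppr_AF_108220 and UF_Ppr_AF_108285 were chosen after their values were seen.

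With the outlier spots kept, 0 probes passed between eggs and mature ovary, as on scan day 1 alone. The count was 9 with slide as a fixed block. It was 0 without egg array 1, 14 without egg array 2 and 7 without egg array 3. These counts treat all arrays as independent, although 3 egg arrays each lay next to 1 mature array. With those pairs, picked from the data, as a block, the count was 111 (94 lower, random block) or 54 (42 lower, fixed block), and without egg array 1 it was 288 (247 lower) or 0. Limma on the 3 differences within pairs called 0 of 12136 probes (smallest adjusted p = 0.323, 698 at an unadjusted p under 0.05).

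On scan day 1, each of 3 egg arrays lay next to 1 mature ovary array among the 276 pairs of arrays, after each probe was centred on its median. Across the 9675 probes, which are not independent replicates, the correlation was 0.844 for mature array 4 with egg array 3, 0.802 for mature array 2 with egg array 2, and 0.654 for mature array 1 with egg array 4. The next pair, pre-vitellogenic arrays 3 and 4, had 0.601. The median was 0.030 over pairs of the same stage and -0.025 over pairs of different stages. The SD of the log2 difference was 0.270, 0.313 and 0.394 in the 3 mature and egg pairs, and at least 0.561 in all other pairs.

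**Figure D3:**
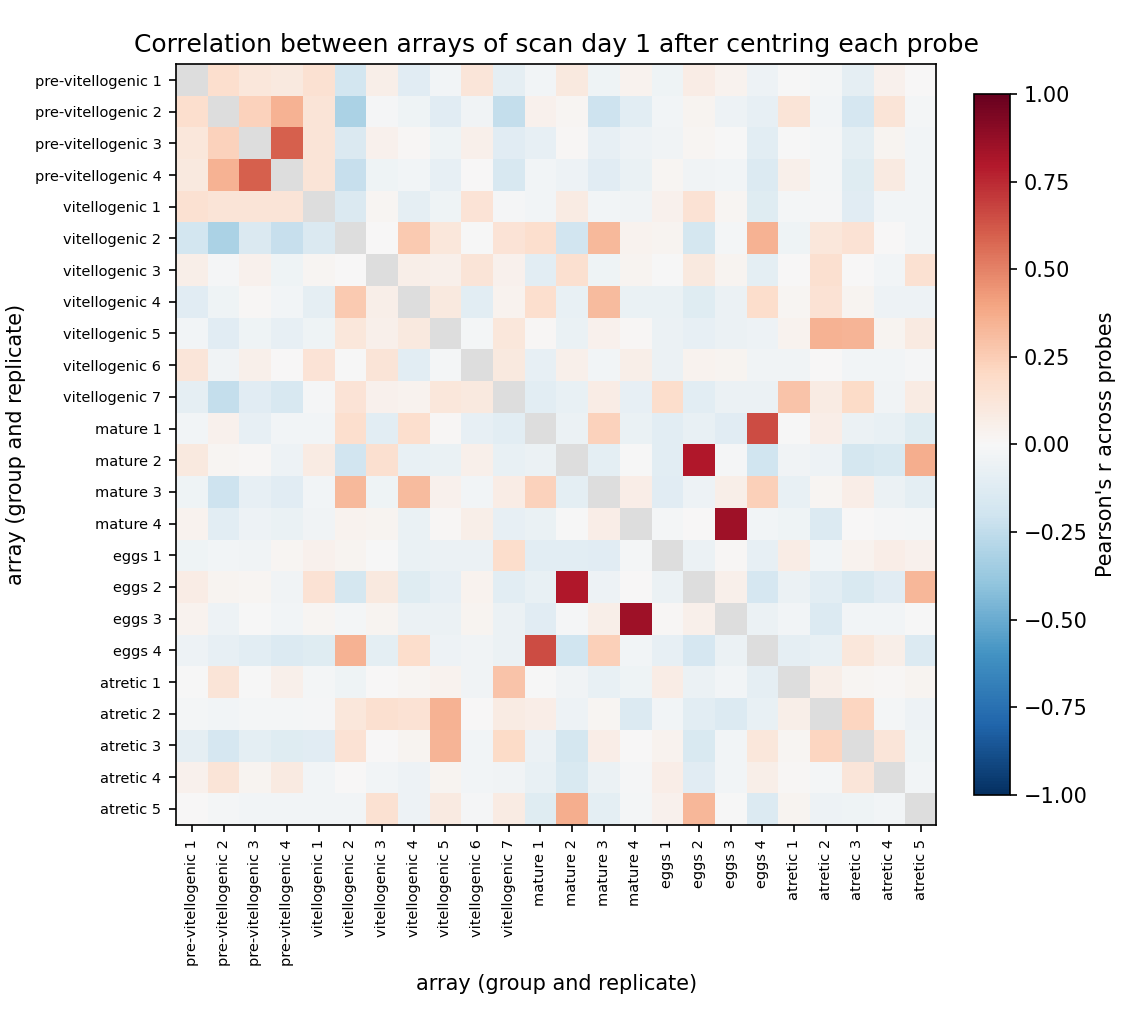
Pearson correlation across 9675 probes between the 24 arrays of scan day 1, each probe centred on its median, with the diagonal in grey. The pairs of mature array 4 with egg array 3 (0.844), mature array 2 with egg array 2 (0.802) and mature array 1 with egg array 4 (0.654) have the highest values.

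Atretic ovary, in which follicles degenerate, was compared with the mean of the 3 other ovary stages. With limma, 0 of 13074 probes passed, the smallest adjusted p was 0.647, and 555 probes (4.25%) had an unadjusted p under 0.05, of which 143 were higher and 412 lower. The median change of all probes was -0.04. It was -0.41 with spike-in scaling and 0.18 with normexp and the 75th percentile, so the split by direction is not read as a result. With normexp and quantile normalization 1 probe passed. Against vitellogenic ovary 0 of 13128 probes passed (smallest adjusted p = 0.999, 380 at an unadjusted p under 0.05), and this count was 0 in every other fit. Against mature ovary 0 of 13210 passed (smallest adjusted p = 0.974, 580 at an unadjusted p under 0.05), with 1 probe without mature array 6.

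Against pre-vitellogenic ovary 1 of 13225 probes passed, and 1267 (9.58%) had an unadjusted p under 0.05. UF_Ppr_AF_100871 (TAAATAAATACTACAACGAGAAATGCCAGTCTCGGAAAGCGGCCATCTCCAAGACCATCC), chosen after its values were seen, was well above background on 3 of 6 pre-vitellogenic and 0 of 7 atretic ovaries. Values not above background enter both sides, so no lower bound on the fold is given. The measured log2 change of this probe was -1.92 (limma, adjusted p = 0.0176). With normexp and the 75th percentile its difference was 0.18 in the other direction (adjusted p = 0.841), and it passed in 35 of 48 other fits, within a range of 0.00122 to 0.841. The count was 0 with slide as a fixed block, 4 on scan day 1 alone and 0 on scan day 2 alone. It was 0 without pre-vitellogenic array 3, 4 or 6 or atretic array 2 or 5, 4 without pre-vitellogenic array 5, 3 without mature array 4, and 2 without egg array 1 or atretic array 6.

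Across the 4 ovary stages, 4 of 13074 probes differed in the F test, all 4 also called between vitellogenic and pre-vitellogenic ovary, and 1126 (8.61%) had an unadjusted p under 0.05. Besides UF_Ppr_AF_100871 and UF_Ppr_AF_108285 these were UF_Ppr_AF_117721 and UF_Ppr_AF_104194, all chosen after their values were seen. UF_Ppr_AF_117721 (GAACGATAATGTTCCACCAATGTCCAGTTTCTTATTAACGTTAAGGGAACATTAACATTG) averaged -4.41 in pre-vitellogenic, -1.44 in vitellogenic, -2.51 in mature and -2.29 in atretic ovary, and -2.74 in eggs (adjusted p = 0.0367). UF_Ppr_AF_104194 (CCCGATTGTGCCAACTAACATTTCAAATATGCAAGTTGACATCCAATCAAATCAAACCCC) averaged -8.03, -4.17, -4.11 and -6.59 in the same ovary stages, and -7.22 in eggs (adjusted p = 0.0367), and was well above background on 3 of 6 pre-vitellogenic, 4 of 7 atretic and 3 of 4 egg arrays, so that the lower means are not exact levels. The count was 0 with scan day as a block, 2 with slide as a fixed block, 8 on scan day 1 alone, and 0 without pre-vitellogenic arrays 2, 3 and 4 or with the mature and egg pairs as a block. It was 0 without pre-vitellogenic array 2, 3 or 4, vitellogenic array 2, 3, 5 or 7, mature array 1, egg array 2, or atretic array 5 or 7. It was 1 without vitellogenic array 4 or egg array 4, 2 without mature array 2 or atretic array 3 or 4, 7 without pre-vitellogenic array 1, 8 without atretic array 2, and 25 without egg array 1. Egg arrays are in none of these stages and act on the count only through the shared estimate of spread.

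Across all 5 groups 9 of 12984 probes differed, and 1198 (9.23%) had an unadjusted p under 0.05. The 9 included the 4 of the ovary stages, 6 of the 38 between vitellogenic and pre-vitellogenic ovary, and the 4 between eggs and mature ovary, of which 3 rest on egg array 1 alone. With the outlier spots kept, 8 probes differed, 6 of them among the 9. No probe passed with spike-in scaling or with replicate number as a block. The count was 15 with slide as a fixed block, 4 on scan day 1 alone, and 29 or 54 with the mature and egg pairs as a random or fixed block. It was 4 without pre-vitellogenic array 4 or vitellogenic array 2, 5 without pre-vitellogenic array 2 or 5 or atretic array 6, 17 without egg array 1 and 20 without egg array 2.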

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

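The tests of the egg array as an ovary sample, of the array pairs, of slide, of pre-vitellogenic arrays 2, 3 and 4 together and of scan day 2 were chosen after the results were seen, and those of the ovary sample and of one RNA were replaced after a first version had been seen; those of the amount of RNA, of scan day as a block and of pre-vitellogenic arrays 2 and 3 were fixed before the values they measure, though the counts of probes under the last 2 had been seen. In 79 groups of values, 6 values lay farther from the rest of their group than a 95% limit for the gap allows, and chance gives about 1 in 20 groups, or 4.

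Egg array 1 lay apart from the other 3 egg arrays in its spike-in level (2.39 in log2 over the 75th percentile, nearest other -0.97) and in the SD of its deviations over the brightest 25% of probes (1.14, nearest other egg array 0.304). Too little labelled RNA stays open. That SD was 2.42 times the highest SD among the other arrays, against the prediction that dim signal leaves bright probes close to the rest. Egg array 1 also had the lowest 75th percentile (821), the fewest saturated probes (15) and the lowest share of probes well above background (73.3%). These values and its spike-in level go with little labelled RNA, so the SD does not settle it. An ovary under an egg label stays open: over 28 probes lower in the other eggs its level was -1.43 in log2 relative to the mature mean, below the lowest vitellogenic or mature array (-1.14) by less than their SD (0.607), and pre-vitellogenic and atretic arrays reached -1.77 and -2.06. The -1.14 was that of mature array 5, on scan day 2. On scan day 1, that of egg array 1, the lowest vitellogenic or mature level was -0.77. The SD was not taken for scan day 1 alone, and it includes mature arrays on which the 28 were picked. The test therefore cannot decide for a vitellogenic or mature ovary. The test seen first, its highest correlation with any other array (0.175, lowest -0.115), was dropped because arrays of 1 stage also correlate near 0. Degraded RNA and a real difference in the eggs also stay open, as untested.

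The 38 probes called between vitellogenic and pre-vitellogenic ovary had a median change of 1.91 in log2, in size. With scan day as a block the median was 1.86, 97.4% of the first, although the count fell from 38 to 22. With slide as a fixed block it was 2.00, 105% of the first, with all 38 in the called direction and 24 calls (7 of the 38). Without the 2 pre-vitellogenic arrays with the lowest spike-in level it was 1.83, 95.6%, where the count fell to 1 with fewer arrays in the group. Without arrays 2, 3 and 4, apart on the third component, it was 1.75, 91.3%, with all 38 in the called direction. The count then fell to 0 as the median SE rose from 0.397 to 0.471. For these 38, neither scan day, slide nor those arrays alone made the whole measured difference. The 38 were picked for that difference on the same arrays, and scan day 2 held no vitellogenic ovary. This favours medians near the first, so the source is not settled. Of the 145 probes called on scan day 1 alone, 84 (57.9%) kept on day 2 the sign of the pre-vitellogenic difference from mature and atretic ovary, with a median of 0.058 there against 1.25 on day 1, where the probes were picked, which argues against a difference of that size on day 2 for these 145 as a set (90th percentile 0.707). The 38 went the other way, with 35 in the called direction on day 2 and a median of 0.857 there against 1.44 on day 1, but the day 2 arrays took part in picking them. A stage difference stays open, as a hypothesis.

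Mature arrays 4, 2 and 1 each lay next to an egg array, 3, 2 and 4. A shared slide is argued against, since only 1 of the 3 pairs was on 1 slide. One RNA on both arrays of a pair stays open. Among 11028 probes well above background on all 6 arrays, 5 were at least 2-fold lower in eggs in all 3 pairs and 0 at least 2-fold higher (exact binomial p = 0.0625). With 5 probes this p could not be lower, and probes are not independent, so the count could not decide. Limma on the 3 differences called 0 of 12136 probes (698 at an unadjusted p under 0.05). Over all 12136 probes, seen first, 28 were lower and 0 higher, with 64 in mixed directions, but 16 of the 28 were not well above background on any egg array, the pairs were picked from the data, and 2-fold was 1 of 4 thresholds looked at (the others gave 115 and 5, 13 and 0, and 10 and 0). An ovary and the eggs expressed from the same fish may also account for the pairs, but no label ties eggs to ovaries, and this was not tested.

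UF_Ppr_AF_109599 on vitellogenic array 2 had a log2 level of -5.86 and was the lowest of the 7 vitellogenic arrays. UF_Ppr_AF_111654 on mature array 6 had -2.27, against -3.05 for the nearest mature array. UF_Ppr_AF_115695 on mature array 6 had -5.60, against -4.01 for the nearest. UF_Ppr_AF_108220 on atretic array 1 had 1.92, against 2.08, among the 4 atretic arrays with a value.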

How the results depend on the processing

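Fits on 1 scan day or slide, without pre-vitellogenic arrays 2 and 3 or 2 to 4, with the 3 mature and egg pairs as a block, and with at least 2 values in every group were chosen after the data were seen; all others were planned. The main counts were 9 (5 groups), 4 (4 ovary stages), 38 (vitellogenic against pre-vitellogenic), 4 (eggs against mature) and 1 (atretic against pre-vitellogenic). Mature against vitellogenic, and atretic against vitellogenic and against mature, gave 0 in every fit with all replicates. Where the text below gives a count and no reason, the cause was not tested.

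The count for 5 groups was 0 with spike-in scaling, 4 with normexp and the 75th percentile, 15 with slide as a fixed block, 0 with the replicate block, 2 at an adjusted p of 0.01, 4 on scan day 1 and 5 without pre-vitellogenic arrays 2 and 3. That for 4 ovary stages was 1 without scaling, 0 with spike-in scaling, 0 with normexp and the 75th percentile, 2 with a trend, 16 with array weights, 19 on the compared arrays, 8 with slide as a random block (correlation 0.213), 2 as a fixed block, 0 with scan day as a block, 0 with the replicate block, 0 at 0.01, 8 on scan day 1 and 0 without the 2 arrays.

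Vitellogenic against pre-vitellogenic gave 70 with median centring, 14 without scaling, 0 with spike-in scaling, 5 with normexp and the 75th percentile, 119 with array weights (92 higher), 88 on the compared arrays (77), 58 with slide as a random block (45), 24 as a fixed block, 22 with scan day as a block, 1 at 0.01, 145 on scan day 1 and 1 without the 2 arrays. Eggs against mature gave 7 with normexp and quantile normalization, 9 with slide as a fixed block, and 0 with outlier spots kept, array weights, the compared arrays, the replicate block, scan day 1, and at least 2 values, the last with 3 of the 4 probes no longer tested. Atretic against the mean of 3 gave 1 with normexp and quantile normalization.

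Atretic against pre-vitellogenic gave 2 with quantile normalization, outlier spots kept or the compared arrays, 8 with array weights, 4 on scan day 1, and 0 without scaling, with spike-in scaling, normexp and the 75th percentile, the strict filter, a trend, slide as a fixed block, the replicate block, 0.01, scan day 2, or without the 2 arrays. UF_Ppr_AF_100871 reversed to 0.18 with normexp and the 75th percentile. Leaving out 1 array at a time gave 4 to 20 (5 groups), 0 to 25 (4 stages), 3 to 191, 0 to 1 (mature against vitellogenic), 0 to 14 (eggs), 0 to 0 (atretic against 3), 0 to 4, 0 to 0 and 0 to 1 (atretic against pre-vitellogenic, vitellogenic and mature).

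Without pre-vitellogenic arrays 2, 3 and 4 the counts were 4 (5 groups), 0 (4 stages), 0 (vitellogenic against pre-vitellogenic) and 0 (atretic against pre-vitellogenic). With the pairs as a random block (correlation 0.768) they were 29 (5 groups), 0 (4 stages), 111 (eggs) and 0 (atretic against pre-vitellogenic), and as a fixed block 54, 0, 54 and 0. With egg array 1 also left out they were 105, 16, 288 and 0 as a random block, with 123 for vitellogenic against pre-vitellogenic, and 5, 21, 0 and 6 as a fixed block, with 206; the pairs were picked for being close, which lowers the spread within them.

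Relative to the main scaling, spike-in scaling moved the median of all probes by -0.28 (vitellogenic against pre-vitellogenic), -0.55 (eggs) and -0.37 (atretic against 3), no scaling by 0.13, -0.41 and -0.16, and normexp with the 75th percentile by -0.06, 0.22 and 0.22; median centring moved the first 2 by -0.11 and 0.14. Same-numbered arrays of different stages had a median correlation of 0.021 (53 pairs), others -0.005 (304), over both scan days. For atretic with pre-vitellogenic and for atretic with mature ovary, 4 of 6 same-numbered pairs exceeded 0.1 (highest 0.417 and 0.432, lowest -0.164 and -0.208). These values span both scan days. Within scan day 1, with each probe centred there, such pairs ranged from -0.097 to 0.087 and from -0.054 to 0.068, so none exceeded 0.1. So no 2 stages were paired by number throughout, and pairs that do not follow the numbers are not covered by this check. Slide 2 had no stage with over 1 array and could not be fitted. On the other slides of scan day 1, every comparison had a group of 1 array, so those counts decide nothing and are not given. The alternatives for gene lists (camera with an estimated correlation, fry, other choices of probe per gene) were not run, since no probe has a gene name. On average 80.2% of probes were well above background, and for the others no fold beyond a bound can be given.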

Other observations

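The set of probes below and its tests were chosen after the array pairs were seen, and that of sensitivity was replaced after a first version had been seen, since picking the set for falling fixed much of its outcome; the regroupings of arrays were planned, except those for 5 groups with at least 2 values or with outlier spots kept. Over the 28 probes at least 2-fold lower in eggs in all 3 pairs of a mature and an egg array, pre-vitellogenic ovary was lower than vitellogenic ovary. The median log2 level relative to the mature mean averaged -1.16 ± 0.49 (SD, n = 6) in pre-vitellogenic, 0.01 ± 0.41 (n = 7) in vitellogenic, 0.05 ± 0.83 (n = 6) in mature and -0.78 ± 0.91 (n = 7) in atretic ovary, and -1.64 ± 0.29 (n = 4) in eggs. The values for egg arrays 2, 3 and 4 and for mature arrays 1, 2 and 4 (1.19, 0.37 and 0.48) follow from how the set was picked. These mature arrays are also part of the mature mean used as 0, so levels below 0 follow in part from the picking. Egg array 1 was at -1.43. The other mature arrays, 3, 5 and 6, were at 0.00, -1.14 and -0.61, the last 2 on scan day 2, where pre-vitellogenic arrays 5 and 6 were at -0.99 and -0.84. Vitellogenic ovary was 1.17 above pre-vitellogenic ovary (two-sided exact permutation p = 0.00175, adjusted over 4 tests 0.007), and 1.29 above it on scan day 1 (exact p = 0.00606, adjusted 0.0121). The difference between vitellogenic and atretic ovary was 0.80 (exact p = 0.0583, adjusted 0.0777), and 0.67 on scan day 1 (exact p = 0.149, adjusted 0.149). These 4 permutation tests treat the arrays as exchangeable and ignore slide. On egg array 1, which had no part in picking the set, 11 of the 28 (39.3%) were at least 2-fold below the mean of the 3 other mature arrays, against a median of 31.6% of probes as bright.

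UF_Ppr_AF_104194 and UF_Ppr_AF_108285, which differed among ovary stages, belong to this set. Of the 28 probes, 16 were not well above background on any of the 3 egg arrays, so the size of their changes is not known. Lower sensitivity of the egg arrays for dim probes stays open, since no more than 5 of the 28 were well above background on all 3 egg arrays.

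Each count was set against regroupings of the same arrays, 100 groupings with the real one included. These groupings treat the arrays as exchangeable, though scan day, slide and the mature and egg pairs link them. Under 5 of the 100 were as large for the 5 groups (1 grouping, 9 probes, highest other 6) and the 4 ovary stages (2 groupings, 4 probes, highest other 42). The same held for vitellogenic against pre-vitellogenic ovary (3 groupings, 38 probes, highest other 110). These ranks were not adjusted over the results tested, so they do not exclude chance. With scan day as a block the counts were 0 for the 4 ovary stages and 22 for vitellogenic against pre-vitellogenic ovary. For the 5 groups, 3 of the 9 probes rest on 1 egg array. With at least 2 values in every group, 1 grouping was as large (6 probes, highest other 3). With the outlier spots kept it was also 1 (8 probes, highest other 3). More groupings were as large for eggs against mature ovary (21 groupings, 4 probes, highest other 56) and atretic against pre-vitellogenic ovary (8 groupings, 1 probe, highest other 3). For the 4 comparisons with 0 probes all 100 groupings were as large, with highest others of 1 for mature against vitellogenic ovary, 1 for atretic against the mean of 3, 3 for atretic against vitellogenic and 267 for atretic against mature ovary. The grouping with 267 put all 4 arrays of scan day 2 on the mature side, so it follows the scan day. The groupings with 42, 56 and 110 probes, several times the real counts, point to a structure of the arrays that was not traced.

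Between scan days, the difference of a stage from another was compared across probes, which are not independent replicates. The correlation was -0.00035 for pre-vitellogenic ovary minus the mean of mature and atretic ovary, -0.0034 for pre-vitellogenic minus mature, 0.159 for atretic minus mature and 0.0609 for atretic minus pre-vitellogenic ovary. Over 404 contigs with both probes tested, the median correlation of the probes of a contig across the 30 arrays was 0.171, against 0.070 for shuffled pairs.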
